A study of Nothobranchius furzeri with 10 samples.

How the data were processed

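Total RNA of muscle from exercised male Nothobranchius furzeri of the strain GRZ was made into 10 libraries with a TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4, without parameters. The genome build, the annotation and the strand setting are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and the treatment of reads shared between near-identical genes is likewise not given.

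The authors deposited a table of whole-number read counts for 26739 genes in 10 libraries, which was used as deposited. Its columns carry the titles of the samples, and 0 columns were left unused. The authors also deposited a table of RPKM values for the same genes and libraries, with the same zeros. The way these RPKM values were made is not given in the sources used here. The values were compared with the count divided by 1 length per gene and by a count total, where the 10 totals run on down the rows of each column instead of staying with their own library. Lengths worked out on that basis were resolved to 0.1 bases for 32136 values, and 100% of these lay within 0.1 bases of a whole number, against 27.5% with the library's own total. Lengths rounded to whole bases were obtained for 20593 genes, including all 14109 tested ones (median 2947 bases). Of the 205930 values of these genes, 100% were remade from the count, that length and the running totals to within 0.001 RPKM or 0.1%. With the own total it was 16.5%. That length was itself worked out with the running totals and no other was fitted, so a low value was built in there. RPKM was then recomputed by multiplying each deposited value by its running total over the library's own total. The gene lengths and the recomputed RPKM therefore derive from the deposited RPKM values. So do the results that use them: RPKM levels and ranks, groups by RPKM or length, and removal of a length trend. As deposited, the values entered only the RPKM check, its comparisons with recomputed RPKM at the end of the report, and alternatives to the main settings.

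All 10 libraries form 1 group from the perturbation label, numbered 1 to 10 in accession order. No pair of libraries differed by sampling noise alone, as 1 library sequenced again would: the chi-square of their counts per degree of freedom, about 1 under such noise, was 18.0 to 129 over genes with at least 20 counts in a pair. Separate libraries from the same fish are not excluded by this. Depth was 24844696 to 42170825 counts per library, at which 3 counts, the limit that a count of 0 allows, correspond to 0.0711 to 0.121 CPM.

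Genes were kept by edgeR's filterByExpr with 1 group, which left 14109. Log2 CPM used TMM-scaled library sizes and a prior count of 2. TMM factors lay between 0.885 and 1.15, or -0.18 to 0.21 on the log2 scale. Scaling by TMM instead of the library total moved the log2 CPM of all genes of a library by about this amount in the opposite direction. Common and gene-wise dispersions came from edgeR's estimateDisp with an intercept, and were also estimated without moderation (prior df of 0) after the data were seen. The index of dispersion test summed the squared Pearson residuals of the counts around the scaled gene mean and used the Benjamini-Hochberg adjustment at 0.05. It was tested on simulated data drawn from the means and library sizes of the real genes. Spread for abundance was the SD of log2 CPM minus a lowess trend (fraction 0.3) on the mean. Principal components were taken of log2 CPM centred per gene. The tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 (size factors as an alternative), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

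Before the data were examined, 27 gene lists, 30 paralog or isoform pairs and 24 pairs of lists were fixed by gene symbol, together with tests of their levels, spread and co-variation and of genes following a slow muscle or an immediate early score. None of these tests could be run, because 0 of the 26739 identifiers matched the table of names. The identifiers were not translated by other means. The test of spread beyond counting noise, the ranking by spread and the abundance description were run as planned. The rule for named genes allowed the 15 most abundant genes, and the 20 most variable and 10 most stable genes with a symbol; the texts name 5 of the first kind and 2 of each of the others, the latter without the symbol requirement. A further 3 genes at 0 in some libraries and high in others are named in the closing section and were chosen after their values were seen. The RPKM check, the principal components and the BCV summary were added after the data were seen. Alternatives were DESeq2 size factors, the library total, no filter on low counts, leaving out each library in turn, thinning, removal of abundant genes, removal of a length trend, and RPKM in place of counts.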

Results

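RNA from muscle of the turquoise killifish Nothobranchius furzeri, a short-lived annual fish used to study ageing, was sequenced in 10 libraries. All came from males of the inbred laboratory strain GRZ at 10 weeks of age. The perturbation label of all 10 is swim-tunnel, after a device that makes fish swim against a current. The labels put the 10 libraries in 1 group and name no unexercised fish, so no effect of exercise was estimated and no groups were compared. What the design allows is a description of the muscle transcriptome under that perturbation label and of its spread among libraries. The labels do not state that each library came from a separate fish, so the spread and the p-values refer to these libraries. Genes carry only the identifiers of the deposited tables, and 0 of the 26739 identifiers matched the names table used here. The muscle fibre, metabolic, stress and cell type gene lists chosen in advance could therefore not be read, and single genes are given by identifier.

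Between 24844696 and 42170825 counts were assigned to genes per library, with a mean of 30519671 ± 5103722 (SD, n = 10). Between 19719 and 20553 genes had at least 1 count in a library, and 17872 genes had a count in every library. A further 4542 genes (17.0%) were at 0 in every library. Over the 305196713 counts of the 10 libraries together, a count of 0 allows up to 0.00983 CPM for such a gene (3 counts), which covers counting error only.

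A small number of genes made up most of the muscle transcriptome. The most abundant gene, Nfu_g_1_002091, held 14.0% ± 1.06 (SD, n = 10) of all counts and ranged from 12.9% to 16.5%. The next, Nfu_g_1_007569, held 4.84% ± 0.217 (SD, n = 10). The 20 most abundant genes together held 50.6% ± 1.79 (SD, n = 10), and it took between 16 and 25 genes to reach 50% of the counts of a library. Length-scaled levels, computed as RPKM with the count total of the library itself, gave 77212 ± 5863 for Nfu_g_1_002091 and 24438 ± 1094 for Nfu_g_1_007569 (SD, n = 10), whose lengths were 1813 and 1979 bases. By RPKM the order differed: Nfu_g_1_019445, with a length of 342 bases, ranked first at 100267 ± 7191 (SD, n = 10), Nfu_g_1_002091 ranked 2 and Nfu_g_1_007569 ranked 5. The 2 longest of the 20593 genes with a length were among the 20 most abundant by counts. They were 88546 and 67190 bases long and held 1.12% ± 0.185 and 0.969% ± 0.184 of the counts (SD, n = 10).

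**Figure D1:**
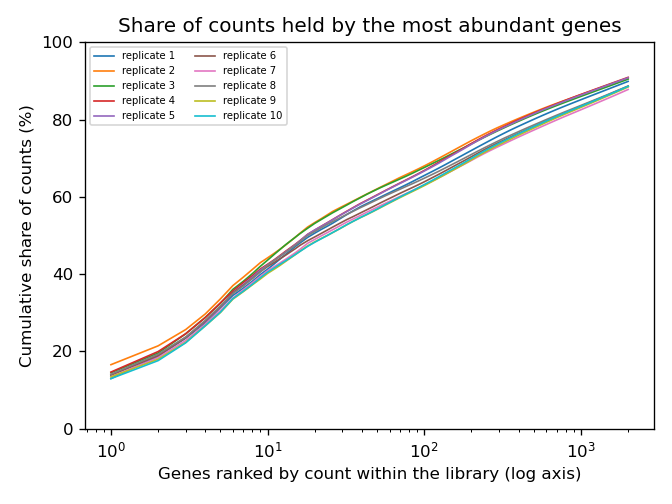
Cumulative share of counts (%) against the number of genes, ranked by count within each library on a log axis; each line is 1 of the 10 libraries. All 10 lines start between 12.9% and 16.5% at the first gene and pass 50% at between 16 and 25 genes.

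Genes were grouped by their mean RPKM. The 78 genes at 1000 RPKM or more held 56.6% ± 1.67 of the counts, and the 307 genes between 100 and 1000 RPKM held 18.2% ± 0.608 (SD, n = 10). The 2310 genes between 10 and 100 RPKM held 14.3% ± 0.808. The 8525 genes between 1 and 10 RPKM held 9.98% ± 1.07, and the 10977 detected genes under 1 RPKM held 0.953% ± 0.127 (SD, n = 10). The median length was 666 bases in the group at 1000 RPKM or more, 1284 bases between 100 and 1000 RPKM, 1650 bases between 10 and 100 RPKM, 2805 bases between 1 and 10 RPKM and 2410 bases in the 9373 genes under 1 RPKM that had a length. Differences in length and spread between these groups of genes were not tested.

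Most genes varied among the libraries by more than counting error. Of 14109 genes with enough counts to test, 12959 (91.8%) varied beyond counting noise and 1150 did not pass the test (index of dispersion test against the chi-square distribution, Benjamini-Hochberg adjusted p below 0.05). The common biological coefficient of variation (BCV), edgeR's estimate of the relative spread beyond counting error, was 0.298. It was fitted to all 10 libraries as 1 group, as was the test above, so it includes the separation of the libraries into 2 sets on the first principal component. The BCV of single genes, which edgeR moderates towards the trend with abundance, had a median of 0.239, with the 10% and 90% points at 0.171 and 0.427. It exceeded 0.5 in 741 genes (5.25%). The low end is set by the moderation, since 0 genes lay under 0.1 with it and 1812 without it. By abundance, the median BCV was 0.196 in the group at 1000 RPKM or more, 0.198 between 100 and 1000 RPKM, 0.222 between 10 and 100 RPKM, 0.234 between 1 and 10 RPKM and 0.273 in the tested genes under 1 RPKM. By gene length, the median BCV was 0.232 in the 3528 genes of up to 1480 bases, 0.248 in the 3528 of up to 2947 bases, 0.245 in the 3526 of up to 5057 bases and 0.234 in the 3527 longer ones. In the simulated check of this test on 14109 genes, 67.2% of the 67 genes with a spread of 0.25 on the log2 scale were called. With a spread of 0.5 it was 94.0% of 67 genes, and 0.0719% of the 13909 genes without added spread were called. Far fewer genes had spread there than were called in the data, which makes the adjusted threshold stricter. These rates therefore do not carry over to the data.

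Among the 5839 genes with a mean of at least 10 CPM, the 20 genes with the most spread for their abundance differed by 15.8-fold to 269-fold between the highest and the lowest library, with a median of 45.9-fold. Their BCV lay between 0.824 and 1.42. The most variable was Nfu_g_1_005737, with 110 CPM ± 145 (SD, n = 10). It reached 387 CPM in replicate 3, 280 CPM in replicate 8 and 257 CPM in replicate 2, against 1.44 CPM in replicate 10 and 2.29 CPM in replicate 7. The second, Nfu_g_1_007538, had 45.8 CPM ± 43.1 (SD, n = 10), with 112 CPM in replicate 3 and 0.614 CPM in replicate 9. At the other end, the 10 most stable genes differed by between 1.11-fold and 1.17-fold across the libraries. Their CV of CPM was 0.0325 to 0.0480, while their BCV without moderation, which leaves counting error out, was at most 0.0248. Counting error was therefore a large part of their spread, and the order among these 10 is partly set by it. The most stable, Nfu_g_1_010036, had 77.7 CPM ± 2.52, and the second, Nfu_g_1_012376, had 21.7 CPM ± 0.764 (SD, n = 10). Which genes ranked as most stable depended on the scaling, since 0 of these 10 were among the 10 most stable when log2 CPM was scaled by the library total in place of TMM, and 7 with DESeq2 size factors. The ranking was set in advance for genes with a symbol, and since no gene had one it was applied to all genes.

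**Figure D2:**
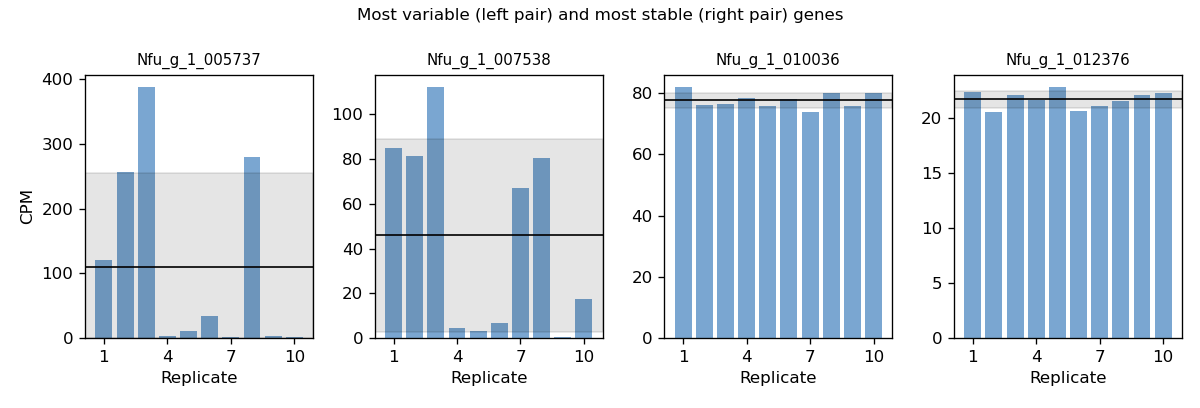
Expression level (CPM, y axis, each panel on its own scale starting at 0) of the 2 most variable and the 2 most stable genes in replicates 1 to 10 (x axis); the line is the mean and the grey band the mean ± SD over 10 libraries. Nfu_g_1_005737 lies between 1.44 and 387 CPM, while Nfu_g_1_010036 lies between 73.8 and 82.0 CPM.

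**Figure D3:**
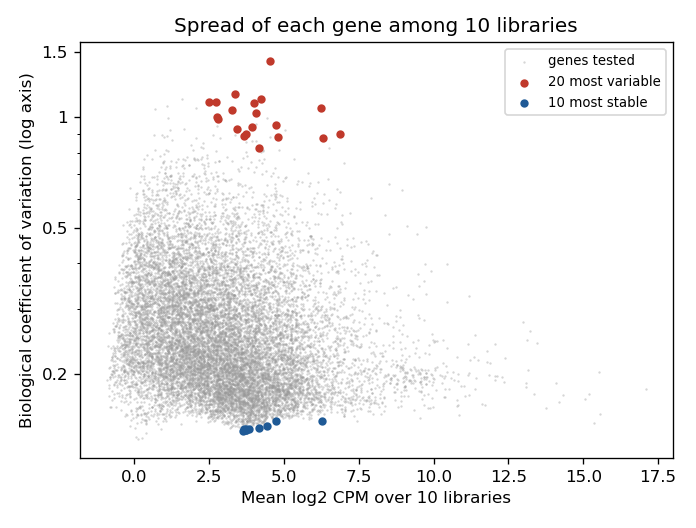
Biological coefficient of variation of each tested gene (y axis, log scale) against its mean log2 CPM over 10 libraries (x axis); grey points are the 14109 genes tested, red points the 20 most variable and blue points the 10 most stable. The red points lie at 0.824 or above and the blue points between 0.140 and 0.148, a level set by the moderation; without it the blue points would lie at 0.0248 or below.

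The expression profiles of the libraries were not spread evenly. Pearson correlations of log2 CPM across the 14109 genes, which are not independent replicates, lay between 0.907 and 0.985 for the pairs of libraries. The first principal component held 53.8% of the variance, the second 12.1% and the third 11.1%. With no filter on low counts, an alternative added after the data were seen, the first held 35.7%. After the values of each gene were shuffled among the libraries, the first component held at most 12.2% in 20 shuffles. Shuffling each gene separately removes all correlation between genes, so a low value was fixed in advance. It does not bear on how the libraries are grouped. On the first component replicates 1 to 5 scored from -50.7 to -27.6 and replicates 6 to 10 from 28.3 to 45.8, with no library between. With no filter the same 2 sets remained, with the gap between them falling from 57.9% to 24.1% of the range of scores. The labels give these libraries the same strain, age, sex, tissue and perturbation, and replicate numbers follow accession order. The sample titles carry the numbers 74 to 78 for replicates 1 to 5 and 80 to 84 for replicates 6 to 10, so the only break in that numbering falls between the 2 sets. The labels do not say what the numbers stand for. Because the libraries lay in 2 separate sets of 5, correlations between gene levels across all 10 are not given with this separation left in. A correlation within a set of 5 would rest on fewer than 6 libraries.

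The 2 sets of libraries were found from the expression values, so they were not compared with each other gene by gene. The composition of the counts also differed among libraries: the TMM scaling factors of replicates 1 to 10 were, in that order, 0.963, 0.915, 0.933, 0.896, 0.885, 1.05, 1.15, 1.08, 1.08 and 1.09. These factors come from the same counts and are not separate evidence. For the median tested gene 44.6% of the variance among libraries followed the first component. This share was over 80% for 2890 genes (20.5%). For the 20 most variable genes its median was 26.4%, and it exceeded 50% in 9 of them. The component was computed from these same genes, so a high share is partly built in. Shuffled genes had a median share of 5.82%, but the component was not computed anew for them, so this value leaves out the fitting.

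**Figure D4:**
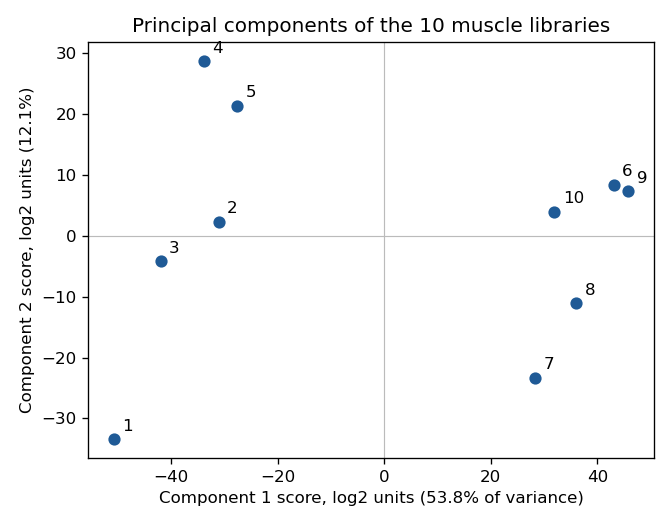
Scores of the 10 libraries, marked with their replicate number, on the first principal component (x axis, 53.8% of variance) and the second (y axis, 12.1% of variance) of log2 CPM; each point is 1 library. Replicates 1 to 5 lie at -27.6 or below on the x axis and replicates 6 to 10 at 28.3 or above.

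Within a gene, the deposited RPKM values were not proportional to the count divided by the library's own total. In 5434 genes with at least 200 counts in every library, the gene length implied by the count, the RPKM value and the library's own total varied among the 10 libraries with a median CV of 23.5%. When the 10 totals were instead repeated down the rows of each column in turn, the implied length varied by at most 0.0716% in any of these genes. Under that scheme 10.0% of the values were divided by the total of their own library, and the divisor ranged from 0.589 to 1.70 times the right one. The library with the highest value differed between deposited and recomputed RPKM in 8755 of the 14109 tested genes (62.1%). The median SD of log2(RPKM + 0.1) among libraries was 0.462 as deposited and 0.336 with the own total. RPKM values given above use the own total.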

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

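All tests in this part were chosen after the result was seen. The outlier test used here (Dixon's) marks about 5% of groups by chance when the values come from a single normal group. Replicate 2 held the highest share of counts in the most abundant gene, Nfu_g_1_002091, at 16.5%, apart from the other libraries. Several measures were screened with this test, so chance is not excluded here.

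Replicate 1 was the outlying library in more genes than any other, and its count stood apart from those of the other 9 libraries. It was outlying in 355 genes, in 219 as the highest and in 136 as the lowest library, while the next library, replicate 6, had 86. In 20 shuffles of the values within each gene no library had more than 88. Over all libraries 684 genes (4.85% of those tested) had an outlying library. The 5% of the test holds for a single normal group, while these libraries lay in separate sets on the first component. The number of such genes can therefore not be set against that 5%. The shuffles keep this number. Shuffling each gene separately also removes all correlation between genes, so a near-even spread over the libraries was fixed in advance. When genes vary together, 1 shared deviation can give 1 library many such genes. The shuffles therefore do not show how unusual the count of replicate 1 is. Replicate 1 had the fewest counts, but after all libraries were thinned to its depth it was still outlying in 324 genes, against 80 in the next, which argues against depth as the cause. Removing a length trend from each library left 380, against 78, which argues against a length bias. RNA of another tissue in that sample may have contributed, but without gene names no markers could be read, and the 219 genes in which it was highest do not decide. No biological explanation was tested, since the labels give 1 group.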

How the results depend on the processing

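No paired analysis was possible because the labels give 1 group. The count of genes varying beyond counting noise was 12948 with DESeq2 size factors, 16282 of 22197 genes with no filter, and 12664 to 12974 when each library was left out in turn. The common BCV was 0.298 with DESeq2 size factors, moved to 0.340 with no filter, and lay between 0.281 (without replicate 1) and 0.305 when libraries were left out. The first component held 35.7% of the variance with no filter, 59.4% with RPKM as deposited and 57.9% with RPKM and the own total; it held 53.2% to 56.1% under the other scalings, thinning and corrections, and 51.5% to 55.6% when libraries were left out. The 20 most abundant genes held 50.3% to 50.8% when libraries were left out. Of the 20 most variable genes 19 remained with DESeq2 size factors, 18 with the library total, 17 with RPKM as deposited and 18 with RPKM and the own total. Of the 10 most stable genes 7 remained with DESeq2 size factors and 0 with the library total, where only the scaling differed; 0 also remained with either form of RPKM, which differs in scaling and offset at once. The alternatives fixed in advance for gene lists, pairs and scores were not run, since no identifier matched a symbol. The alternatives on components and RPKM, the library total for the ranking, those that left libraries out for components and abundant genes, and all alternatives on the BCV were chosen after seeing the data. Of the 22197 genes with a count, 14109 passed the filter, and the others were tested only in the alternative with no filter.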

Other observations

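The test on the most variable genes was planned before its result was seen; the other tests and the genes named here were chosen after their values were seen.

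The 2 longest genes with a known length, Nfu_g_1_019261 and Nfu_g_1_019276, varied among libraries by 16.5% and 19.0% (CV, n = 10) as shares of the counts. The ratio of their shares varied less, by 4.66%, with a mean of 1.17 ± 0.0543 (SD, n = 10) and a highest value of 1.26. These values include the separation of the libraries into 2 sets on the first component. A further 10 genes were at 0 counts in at least 1 library and at 5 CPM or more in another, a level at least 48.7-fold above the limit of 3 counts in the library at 0. In a pair of these, Nfu_g_1_007317 and Nfu_g_1_007316, counts were high in the same libraries, with 296 and 245 in replicate 2 and 376 and 303 in replicate 8. Both were at 0 in replicates 3 and 4. Nfu_g_1_010492 had 719 counts in replicate 7, where its CPM was highest at 26.8, and 835 in the more deeply sequenced replicate 9. It had 268 in replicate 1, against 43 in replicate 5 and 4 or fewer in the other libraries.

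The 2 sets of 5 libraries on the first component were separated by a gap of 57.9% of the range of scores. After thinning to the smallest total the same sets were separated by 58.0% of the range, which argues against depth. Removing the 20 most abundant genes changed the gap from 74.1% to 68.5% with scaling by the library total, which argues against these genes as the whole cause. The gap stayed at 57.9% with TMM. That value could hardly have changed, because TMM trims extreme genes and 20 of 14109 genes weigh little in the components, so nothing is drawn from it. After removal of a length trend it was 57.9%, which argues against length as the whole cause. With no filter on low counts the same sets remained, with a gap of 24.1%, under the bound of 25% that the tests on depth, abundant genes and length used. A sequencing, handling or sampling batch, or a condition that the labels do not record, could each give such a component with 53.8% of the variance, and they cannot be told apart because the labels give 1 group and name no batch. The break in the numbers of the sample titles, 74 to 78 and 80 to 84, falls between the 2 sets, but the labels do not say what the numbers mark.

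The mismatch between deposited RPKM and counts is consistent with totals recycled down the rows during division. With that divisor 100% of the 5434 genes with at least 200 counts per library gave 1 length within 1%, against 0% with the own total and 0% with each of the other 9 starting points of the recycling. With that divisor the implied length of each of these 5434 genes varied among libraries by at most 0.0716% (CV). A gene length set separately for each library, with differences beyond that size, is therefore excluded for these genes. Lengths were whole numbers in 100% of the resolved values, which does not bear on this, since lengths set per library would be whole too. The error changes the ratio of a gene between 2 libraries by up to 2.88-fold, while ratios recomputed from the counts are free of it.

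One hypothesis was that the 20 most variable genes share an axis of variation beside the first component. After removal of that component the median absolute pairwise correlation of the 20 genes was 0.345, against a median of 0.298 for 10000 random lists of 20 genes matched on abundance. This lies at percentile 91.3 of the random lists, short of the level set in advance for a shared axis, and the question stays open.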
